A study of Mus musculus with 8 samples.

How the data were processed

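Mouse liver was profiled by in-situ ChIA-PET, in which chromatin is crosslinked, cut and religated inside permeabilised nuclei before immunoprecipitation, so that a paired-end tag (PET) whose ends map apart records 2 genomic places that lay close together at a bound site. Per the labels' protocols, nuclei were crosslinked with formaldehyde and then EGS, cut with AluI, religated, sheared, pulled down, tagmented with Tn5, amplified by PCR and sequenced in pairs. The antibody recognised the HA tag of a 3HA-tagged REV-ERBα (gene Nr1d1), a nuclear receptor that represses transcription in the circadian clock. Of the 8 samples of the series, 6 were used. They comprised 1 knock-in library at zeitgeber time (ZT) 22 and 1 at ZT10, and 2 libraries for each of 2 constructs at ZT10. In those 4, mice with floxed Nr1d1 and Nr1d2 had received, by adeno-associated virus (AAV), Cre recombinase with either full-length tagged REV-ERBα (WT) or a form labelled delhIDR (written dhIDR), which by its label lacks the hIDR. The 2 anti-CTCF samples were not analysed here.

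Each deposited file lists, for 1 library, pairs of anchor intervals on the same chromosome and the raw counts of PETs joining them, not normalized and not pooled over replicates. The genome build was mm10, per the submitters' processing notes. The aligner, the duplicate filter and the cluster caller were not given in the sources used here. In every file the lowest deposited count was 3, so a loop that a library does not list has 0 to 2 PETs there, and the sum of listed PETs is not the sequencing depth. Unlisted loops entered the models and the ranking of ratios as 0 (with a pseudocount of 0.5 PETs in the knock-in ratios), so fitted values and ratios against 0 serve to rank and are not read as folds. Groups and replicate numbers came from the sample titles.

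Listed PETs on nuclear chromosomes numbered 132709 in the ZT22 and 320427 in the ZT10 knock-in library, 104161 and 204018 in WT replicates 1 and 2, and 178426 and 160635 in dhIDR replicates 1 and 2. Mitochondrial clusters were left out of the main comparisons and kept in 1 alternative. PETs were assigned to 21887 protein-coding genes of RefSeq's GRCm38.p6 annotation, whose coordinates are those of mm10, when an anchor lay within 5 kb of either annotated gene end. The gene table used carries no strand, so both ends replaced the 5′ end that the design had named. A loop near several genes counted for each of them, so neighbouring genes share PETs. All 243 entries of 14 gene lists matched the annotation, 1 of them through a synonym. The lists cover the core clock, lipogenesis, cholesterol and bile acids, glucose, fatty acid oxidation, xenobiotic metabolism, liver transcription factors, secreted hepatocyte proteins and acute-phase genes, and markers of Kupffer, endothelial, stellate, cholangiocyte and lymphoid cells.

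WT and dhIDR libraries were compared by edgeR's quasi-likelihood test with TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05, per gene and per loop. For the latter, overlapping anchors were merged over the 4 libraries. Gene lists were tested with limma's camera at a preset correlation of 0.01, and with fry. Because filterByExpr left at most 1 member of each list, the list tests used all genes with a PET in any of the 4 libraries, which departs from the design. Whole-library measures were compared by exact two-sided permutation tests, whose smallest p with 2 against 2 libraries is 0.333. The knock-in libraries have no replicate. For each gene with at least 30 PETs over both, the ratio of shares of listed PETs was given an exact Clopper-Pearson interval at 95%, PETs were given exact Poisson intervals, and a list's median log2 ratio (pseudocount 0.5 PETs) was placed among 10000 random lists of the same size matched on mean PETs. Shares of matched loops have Wilson intervals. A loop matched when both anchors overlapped by at least 1 bp.

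Named genes followed a rule. For WT against dhIDR it took up to 10 genes per direction, filled by smallest p and given as values where none passed, all tested core clock members, and the 2 members with most PETs of each other list. For ZT10 against ZT22 it took the 10 largest ratios per direction among genes whose interval excluded 1, all core clock members with PETs, and again the 2 leading members of each other list. Up to 5 loops per direction were taken by smallest p. Genes shown for loops by rank, the loops and the window at Npas2, the loops that recurred between AAV libraries and the 10 ZT10 anchors with most loops were chosen after values were seen. Some genes that the rule takes are not reported here.

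Both procedures were tested on simulated data. At the real depth and the real dispersion (0.8945), the edgeR step recovered 0 of 49 simulated 4-fold changes among 735 tested genes and 0 of 78 simulated 8-fold changes among 771. At 10 times that depth and a dispersion of 0.05 it recovered 93% of 200 4-fold changes among 15830 genes and 100% of 200 8-fold changes among 15784. The interval step for the knock-in libraries placed 196 of 196 simulated 8-fold changes outside 1 among 2112 genes, and 96.5% of its intervals held the true ratio. That coverage applies to independent PETs. Real PETs may include copies of single ligation products, and loops with few PETs are not listed. The simulation therefore does not show that the intervals hold for the real counts.

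Alternatives were DESeq2, its size factors in edgeR, total listed PETs, cyclic loess, no filter, at least 20 PETs, windows of 2 and 25 kb, loops of at least 5 PETs, spans over 20 kb, the replicate number as a block, each replicate left out, unlisted loops set to 2 PETs, pairs of 10-kb bins, anchors overlapping by at least 50% of the shorter, thinning to the smallest library, a median ratio over genes as scale, at least 60 PETs, at least 50 PETs and an estimated camera correlation. Chosen after seeing the data were the gene body with 5 kb around it, mitochondrial clusters kept, loops with both anchors at least 700 bp wide, list totals in edgeR, removal of 3.1 to 3.3 Mb of chromosome 11, the ZT10 library thinned to the ZT22 total, and the share of PETs inside ZT10 anchors with its alternatives (ZT10 loops of at least 10 PETs, wide anchors, each replicate left out). Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.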

Results

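Chromatin loops pulled down with HA-tagged REV-ERBα were listed in 6 mouse liver libraries. The knock-in mice, which carry the tag on their own REV-ERBα, gave 40597 loops at ZT22 and 57865 at ZT10, the time of day near the peak of the protein. In mice whose hepatocytes received Cre and a tagged construct by AAV, collected at ZT10, replicates with the full-length construct (WT) gave 31033 and 58102 loops, and those with a form labelled as lacking the hIDR (dhIDR) 47939 and 41981. Listed PETs numbered 132709 at ZT22, 320427 at ZT10, 104161 and 204018 for WT, and 178426 and 160635 for dhIDR. A PET is one sequenced pair joining both anchors of a loop, and every listed loop had at least 3. Nothing in the labels says that the 2 replicates of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Intervals cover counting error only and take each PET as independent. PETs are listed at least 3 to a loop and may include copies of single ligation products, which would make the intervals too narrow.

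At Nr1d1, the gene of REV-ERBα on chromosome 11 (98767932 to 98775377), listed PETs numbered 3 at ZT22, 265 at ZT10, 5 and 3 in the WT replicates, and 5 and 0 in the dhIDR replicates. At Nr1d2, which encodes its paralog REV-ERBβ, on chromosome 14 (18204056 to 18239106), they numbered 7, 0, 0, 8, 0 and 0 in the same order. These counts sum PETs of listed loops near the gene ends and do not measure coverage of the floxed segments. They therefore do not check whether the floxed genes were deleted.

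The ZT10 knock-in library had shorter and stronger loops than the other 5. Its median loop span was 40.1 kb, against 524 kb at ZT22, 953 and 834 kb in WT, and 647 and 1071 kb in dhIDR. Loops over 2 Mb made up 8.33% at ZT10, 39.0% at ZT22, 43.3% and 41.9% in WT, and 38.8% and 44.2% in dhIDR. Mean PETs per loop were 5.54 at ZT10, 3.27 at ZT22, 3.36 and 3.51 in WT, and 3.72 and 3.83 in dhIDR. Of the merged anchors at ZT10, 8.88% joined 5 or more loops, and the other 5 libraries each had under 0.01% of such anchors. Both anchors lay at gene ends for 10.7% of loops at ZT10, 4.06% at ZT22, 3.07% and 2.93% in WT, and 3.77% and 3.00% in dhIDR. The median anchor was 1067 bp wide at ZT10, and 626, 604, 604, 603 and 601 bp wide in the others.

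**Figure D1:**
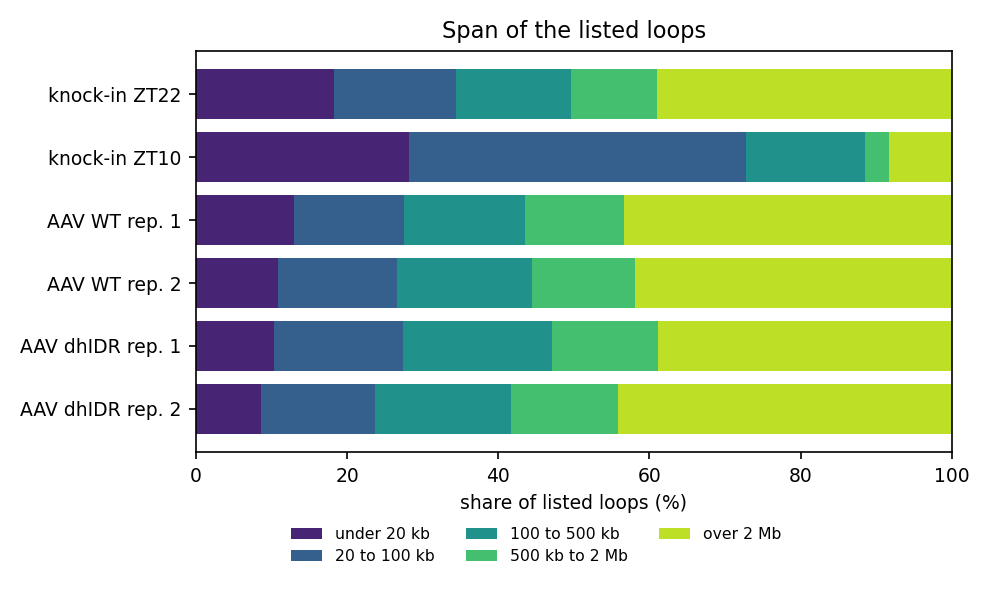
Stacked bars show the share of listed loops (%) in 5 classes of span for each of the 6 libraries. Loops over 2 Mb make up 8.33% in the ZT10 knock-in library and between 38.8% and 44.2% in the other 5.

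**Figure D2:**
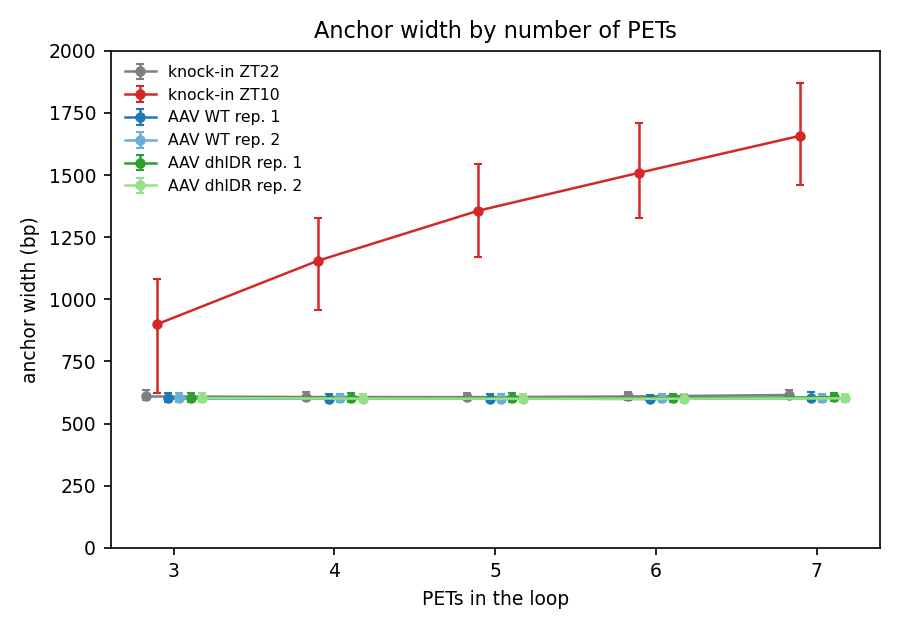
Median anchor width in bp (points, with bars from the 25th to the 75th percentile) is plotted against the PETs in a loop, from 3 to 7, for each library. From 3 to 7 PETs the median grows 1.84-fold in the ZT10 knock-in library and by at most 1.01-fold in the other 5.

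The time-of-day comparison asked which loci REV-ERBα loops at ZT10 and not at ZT22, when little of the protein is present. The most looped genes at ZT10 encode fibrinogen, the clotting protein made by hepatocytes. Fgg (chromosome 3, 83007724 to 83015056) had 1216 PETs (95% interval 1149 to 1286) at ZT10 and 11 (5.49 to 19.7) at ZT22. Fga (83026153 to 83033627) had 1022 (960 to 1087) at ZT10 and was not listed at ZT22. Insulin receptor substrate Irs2 had 498 PETs at ZT10, the ubiquinone biosynthesis gene Coq8a 411, the corepressor gene Tle3 315, Irf2bp2 307, the carboxylesterase gene Ces1e 291, the repressor gene Bcl6 278, Tsku 271, the pioneer factor gene Foxa2 266 and Gm33049 426, and none of these genes was listed at ZT22. With Fga, these are the 10 genes with the largest ratios, and a gene that ZT22 does not list has at most 2 PETs per loop there, so no fold is given.

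Core clock genes followed. Npas2, which encodes a partner of BMAL1 and lies on chromosome 1 (39193702 to 39363240), had 512 PETs (469 to 558) at ZT10 and 10 (4.80 to 18.4) at ZT22, a log2 ratio of 4.34 (3.52 to 5.48) after scaling to total listed PETs. The log2 ratio was 4.97 at Nr1d1 (3.63 to 7.48), 3.59 at Bhlhe40 (304 against 10 PETs), 3.42 at Ciart (90 against 3), 3.41 at Per2 (217 against 8), 3.26 at Nfil3 (173 against 7) and 2.93 at Hlf (174 against 9). ZT22 counts this small lie near the floor of 3 PETs per listed loop. Unlisted loops of up to 2 PETs could change these ratios, and the intervals do not cover that. Cry1 had 79 PETs, Cry2 42, Per1 29 and Dbp 24 at ZT10, all unlisted at ZT22. Tef had 16 against 5 PETs and Bhlhe41 20 against 3, with intervals that include 1. At their gene ends Arntl, Clock and Rora had 0 PETs at ZT10 and 3 at ZT22, but over the gene body Arntl had 259 against 23 (log2 2.19) and Rora 434 against 57 (1.65), and Clock had 3 against 11. Nr1d2 had 0 and 7, and Per3 had none in any library.

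Of 2085 genes with at least 30 PETs over both libraries, 1830 had a higher share of listed PETs at ZT10, 10 at ZT22, and 245 had an interval that includes 1 (exact Clopper-Pearson). There was no replicate, so this compares 2 libraries and not the conditions. The intervals take PETs as independent and may be too narrow, so the number of calls may be too high. The median log2 ratio of these genes was 3.06. With the median ratio over genes as the scale instead, 298 genes were higher at ZT10 and 376 at ZT22, so that 44.2% of the calls were higher at ZT10, against 99.5% with total listed PETs. Relative to that median, Nr1d1 was at log2 1.91, Npas2 at 1.28, Per2 at 0.35 and Nfil3 at 0.20, whereas Hlf (-0.13) lay on the other side. With a 25-kb window 491 genes were higher at ZT22, and over gene bodies 878.

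The 10 genes higher at ZT22 were led by 3 in a region of chromosome 11 from 3105517 to 3258249, handled here as multicopy, that returns below. Eif4enif1 had 6 PETs at ZT10 and 420 at ZT22, Gm51877 9 and 420, and Sfi1 115 and 552, a log2 ratio of -3.53 (-3.84 to -3.24). The others had few PETs, with log2 ratios of -2.03 for Tdrd7 (11 against 19), -1.65 for Fhl3 (13 against 17), -1.58 for Prg3 (16 against 20), -1.46 for Gimap1 (14 against 16), -1.44 for Utp14b (16 against 18), -1.27 for Tent4b (15 against 15) and -1.18 for Acsl3 (16 against 15). Utp14b and Acsl3 share loops. With a 2-kb window Tdrd7 (11 PETs at ZT10 against 3), Utp14b and Acsl3 (each 16 against 3) changed sign, and with only loops whose anchors were both at least 700 bp wide these and Fhl3 and Prg3 had 0 PETs at ZT22, which leaves no ratio.

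**Figure D3:**
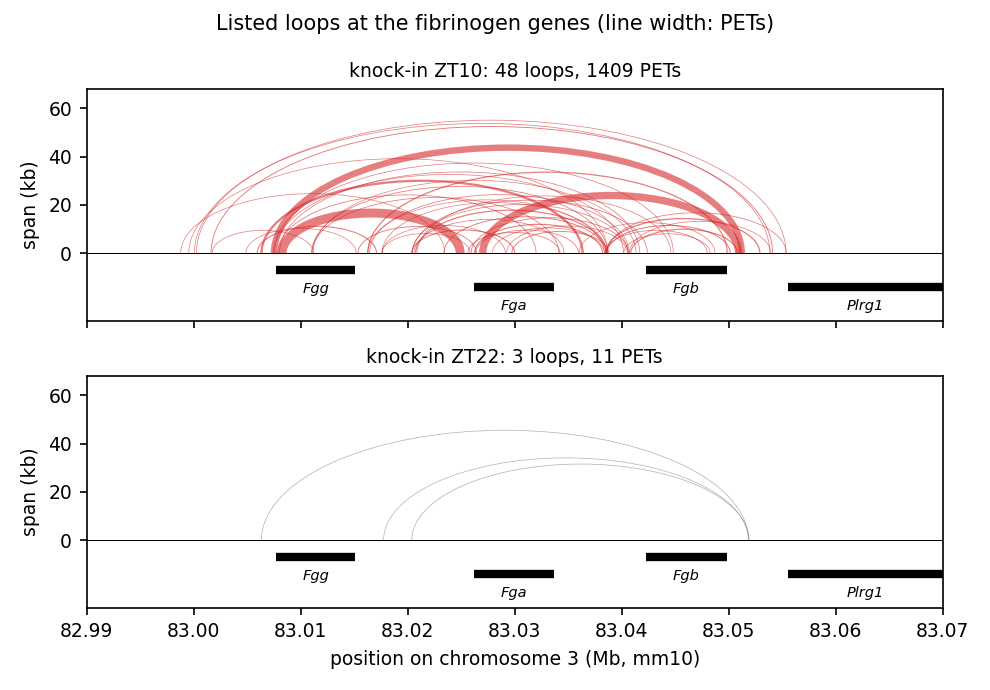
Arcs join the anchors of listed loops on chromosome 3 from 82.99 to 83.07 Mb (height: span in kb; line width: PETs), with ZT10 above and ZT22 under it, over the genes Fgg, Fga, Fgb and Plrg1. The ZT10 library lists 48 loops with 1409 PETs and the ZT22 library 3 loops with 11 PETs.

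Gene lists of liver function held many PETs at ZT10. The 22 measured secreted hepatocyte genes had 18 members higher at ZT10 and a median log2 ratio of 3.95, and their PETs made up 90.3 per 10,000 listed at ZT10 and 5.05 at ZT22. Lipogenesis genes had 18 of 27 higher, among them Insig2 (273 PETs, 242 to 307, against 11, 5.49 to 19.7), which retains SREBP in the endoplasmic reticulum, and Acot1 (162 against 0). Among cholesterol and bile acid genes, 13 of 21 were higher, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 355 against 3 PETs (log2 5.39) and Nr1h4, the bile acid receptor, at 183 against 13 (log2 2.49, and -0.57 relative to the median gene). Glucose genes had 11 of 16 higher, with Irs2 and Igfbp1 (249 against 0) leading. Fatty acid oxidation genes had 14 of 19 higher, with Pdk4 at log2 4.70 (219 against 3) and Acadm at 4.67 (214 against 3). Xenobiotic genes had 13 of 18 higher, with Ugt1a1 at 755 against 19 (log2 interval 3.39 to 4.78, much of it shared with overlapping Ugt1a genes) and Abcc3 at 125 against 0. Liver transcription factors had 13 of 18 higher, with Foxa2 and with Cebpa at log2 4.74 (225 against 3). Acute-phase genes had 16 of 19 higher, with Saa1 at log2 5.27 (326 against 3) and Saa3 at 2.82 (229 against 13, and -0.24 relative to the median gene). The core clock had 10 of 18 higher and none lower. These denominators count members with any PET, while a call needs 30 PETs over both libraries. Members with 30 PETs numbered 18 secreted, 18 lipogenesis, 14 cholesterol and bile acid, 11 glucose and 15 fatty acid oxidation. They numbered 13 xenobiotic, 14 transcription factor, 16 acute-phase and 10 core clock. So few that could be called were not higher, as among all 2085 such genes, of which 1830 were. Relative to the median gene at 3.06, the medians of the cholesterol and bile acid (2.98), glucose (3.02) and acute-phase (2.82) lists lay on the lower side.

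Markers of other liver cell types held fewer PETs at ZT10 than the clock, metabolic and hepatocyte lists, which have more genes. Among random lists of equal size not matched on PETs, the endothelial list (81 PETs at ZT10) stood at percentile 45.9. The cholangiocyte list (32) stood at 23.7, the stellate list (33) at 16.0, the lymphocyte list (18) at 6.4 and the Kupffer list (3) at 0.295. Only the Kupffer list thus lay under percentile 2.5. Kupffer cell genes had 3 PETs in all, and Marco and Clec4f had 0 at ZT10 against 6 and 4 at ZT22. Endothelial genes had 1 of 8 members higher at ZT10, Pecam1 (27 against 3, log2 1.70, and -1.36 relative to the median gene), and Lyve1 had 21 against 3. Among stellate genes none of 11 was called, with Lrat at 0 against 13 and Colec11 at 3 against 12 PETs. Of 6 cholangiocyte genes 1 was higher, Sox9 (32 against 0), and Epcam had 0 against 12. Lymphocyte genes had none of 5 called, with Klrb1c at 6 against 12 and Cd4 at 9 against 3. The 30 PETs that a call needs were met by 1 endothelial, 1 cholangiocyte and 0 Kupffer, stellate or lymphocyte genes. No other member of these lists could be called.

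Against 10000 random lists matched on mean PETs, median log2 ratios stood at percentile 96.1 for fatty acid oxidation, 94.8 for liver transcription factors, 94.4 for secreted proteins, 93.5 for xenobiotic genes, 87.8 for lipogenesis, 86.7 for the core clock, 78.8 for endothelial, 69.5 for cholesterol and bile acid, 56.1 for glucose, 42.9 for lymphocyte, 34.5 for acute-phase, 16.4 for stellate, 13.4 for Kupffer and 11.6 for cholangiocyte genes. None of the 14 lay outside the central 95% of random lists, and with a 2-kb window xenobiotic genes (98.8) and stellate genes (1.86) did, with a 25-kb window secreted proteins (98.4) and Kupffer genes (1.38). Mean PETs come from the same counts as the ratio, so matching removes part of any difference and a place inside that range does not show there is none. Among random lists of equal size not matched on PETs, the 9 clock, metabolic and hepatocyte lists stood at percentiles 99.86 to 100 by ZT10 PETs. By ZT22 PETs they stood at 54.3 to 99.4.

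**Figure D4:**
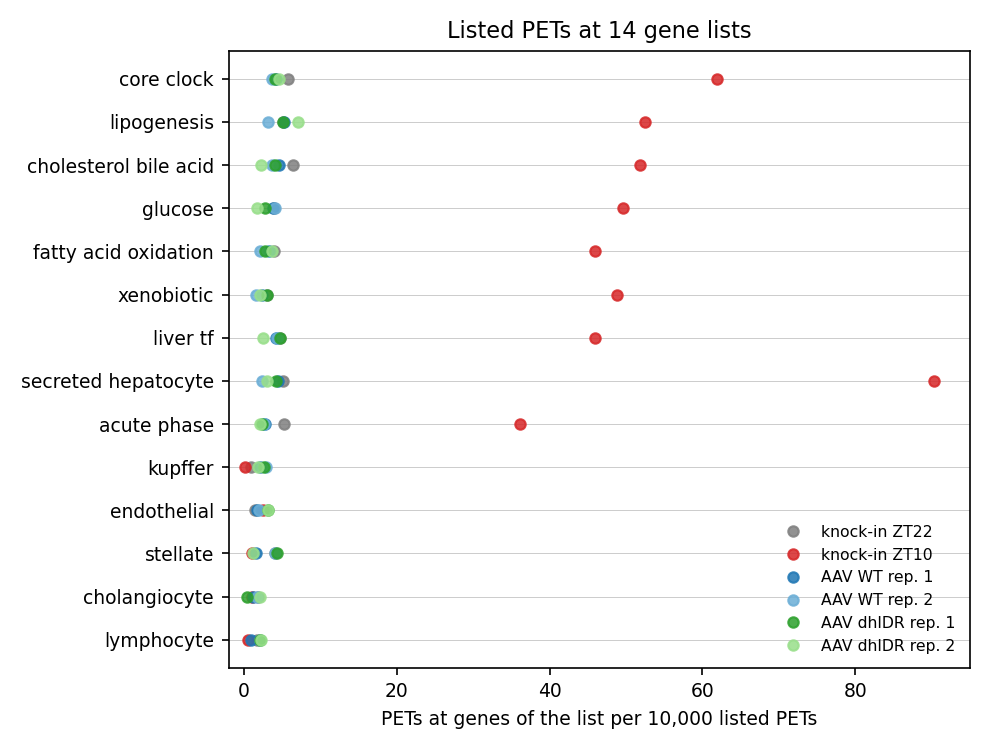
Points give, for each of 14 gene lists and 6 libraries, the PETs at genes of the list per 10,000 listed PETs of that library. In the ZT10 knock-in library the 9 clock, metabolic and hepatocyte lists hold between 36.1 and 90.3, and the 5 lists of other cell types between 0.0936 and 2.53. The 9 lists have 18 to 30 genes and the 5 have 10 to 12, and values are not scaled to list size.

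Few loops themselves were shared between the times of day. Of 57865 loops at ZT10, 561 (0.969%, Wilson interval 0.893 to 1.05%) overlapped a ZT22 loop at both anchors, and 525 of 40597 ZT22 loops (1.29%) overlapped a ZT10 loop. In pairs of 10-kb bins, 2.72% of those at ZT10 were also listed at ZT22. The shared bin pairs outside the chromosome 11 region were 4.32 times as many as after shifting 1 library along its chromosomes. That ratio was 1.67 for the WT pair and 1.68 for the dhIDR pair. Replicates of a construct shared fewer loops still, 0.126% of WT replicate 1 and 0.0271% of dhIDR replicate 1. Low sharing therefore does not set the times of day apart.

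The construct comparison asked what loops change when REV-ERBα lacks the hIDR. No gene passed the test, but Npas2, 1 of the 20 genes with the smallest p, was the one tested clock gene. Npas2 had 23 and 19 PETs in the WT replicates and 4 and 3 in the dhIDR replicates, a log2 difference of 2.84 (SE 0.80, adjusted p = 0.735 in edgeR over 333 genes and 0.0509 in DESeq2). Also higher in WT by value were Rffl (13 and 19 PETs in WT, 0 in both dhIDR libraries), Ephb4 (12 and 15, 0 in both), Shf (13 and 13, 0 in both), Cd44 (8 and 15, 0 in both), Fam210b (9 and 13, 0 in both) and Heatr1 (13 and 18 against 3 and 4). Lower in WT by value were the neighbours Pecr and Tmem169 (0 in both WT libraries, 14 and 19 in dhIDR), Tpm1 (0 in both, 12 and 20), Esrrg (0 and 3 against 18 and 23, log2 -3.43, SE 1.25), Cox15 and Gabra2 (each 0 in both, 13 and 11), Mmp15 (0 in both, 11 and 10), Hhip (0 in both, 12 and 11) and Kif1b (0 in both, 13 and 10). These fitted values for genes at 0 in a group set no bound on a fold. The genes named here all had an adjusted p of 0.735 in edgeR.

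The remaining 3 genes higher in WT by value lie in the chromosome 11 region. That region was handled as multicopy and removed in 1 alternative, though copy number was not measured here. Without it edgeR called 0 of 369 genes (smallest adjusted p = 0.976). Gm51877 had 411 and 92 PETs in WT and 9 and 6 in dhIDR, Eif4enif1 395 and 58 against 9 and 4, and Sfi1 451 and 152 against 23 and 12 (log2 4.44, SE 1.60), and these neighbours share loops. The whole region took 0.888% and 0.422% of PETs in WT, 0.0874% and 0.0579% in dhIDR, and 0.194% at ZT10 and 0.913% at ZT22 in the knock-in libraries. Mitochondrial clusters, left out of the main tests, made up 1.15% and 0.494% of PETs in WT against 0.206% and 0.0939% in dhIDR.

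edgeR called 0 of 333 genes, with 22 at an unadjusted p under 0.05, and DESeq2 called 4 with higher values in WT. These were Sfi1 and Gm51877 (adjusted p = 0.000505 in DESeq2), Eif4enif1 (0.00244) and Rffl (0.0349). Without WT replicate 2, edgeR called Sfi1, Gm51877 and Eif4enif1, with adjusted p from 5.81e-05 to 0.00284 that take the lone WT library to vary like the dhIDR pair, and over gene bodies it called Sfi1 alone (log2 3.14, SE 0.28). The log2 CPM of WT replicates correlated at 0.0719 across tested genes, which are not independent replicates, and that of dhIDR replicates at -0.165. The biological coefficient of variation was 0.946, and in simulation at this depth and spread the test recovered 0 of 78 simulated changes of 8-fold among 771 genes, so differences of that size were not detectable.

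Loops at Npas2, looked at after its counts were seen, joined its low-coordinate end to the same places beyond it in both WT libraries. One joined an anchor on chromosome 1 at 39191567 to 39193867, over that gene end, to 39025127 to 39026405 with 5 and 4 PETs, and another joined it to 39066777 to 39068514 with 5 and 6. Neither was listed in a dhIDR library, and both overlapped ZT10 knock-in loops at both anchors. From 39 to 39.25 Mb, WT replicates listed 9 loops with 32 PETs each, dhIDR replicate 1 none and dhIDR replicate 2 listed 2 loops with 6 PETs. Of the PETs at Npas2, 17 and 10 in WT and 0 and 3 in dhIDR were in loops that matched a ZT10 loop. A WT replicate 2 loop of 6 PETs in its count of 19 spans 53714 kb. With only loops whose anchors were both at least 700 bp wide, Npas2 had 17 and 10 PETs in WT against 0 and 3 in dhIDR. As a share of all wide-anchor PETs the ratio, WT over dhIDR, was 2.40 (counting interval 0.737 to 12.3). With TMM factors, which the 4 genes left to test alone set, the edgeR log2 value of Npas2 took the opposite sign, at -1.15. Over the gene body it was 0.52.

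**Figure D5:**
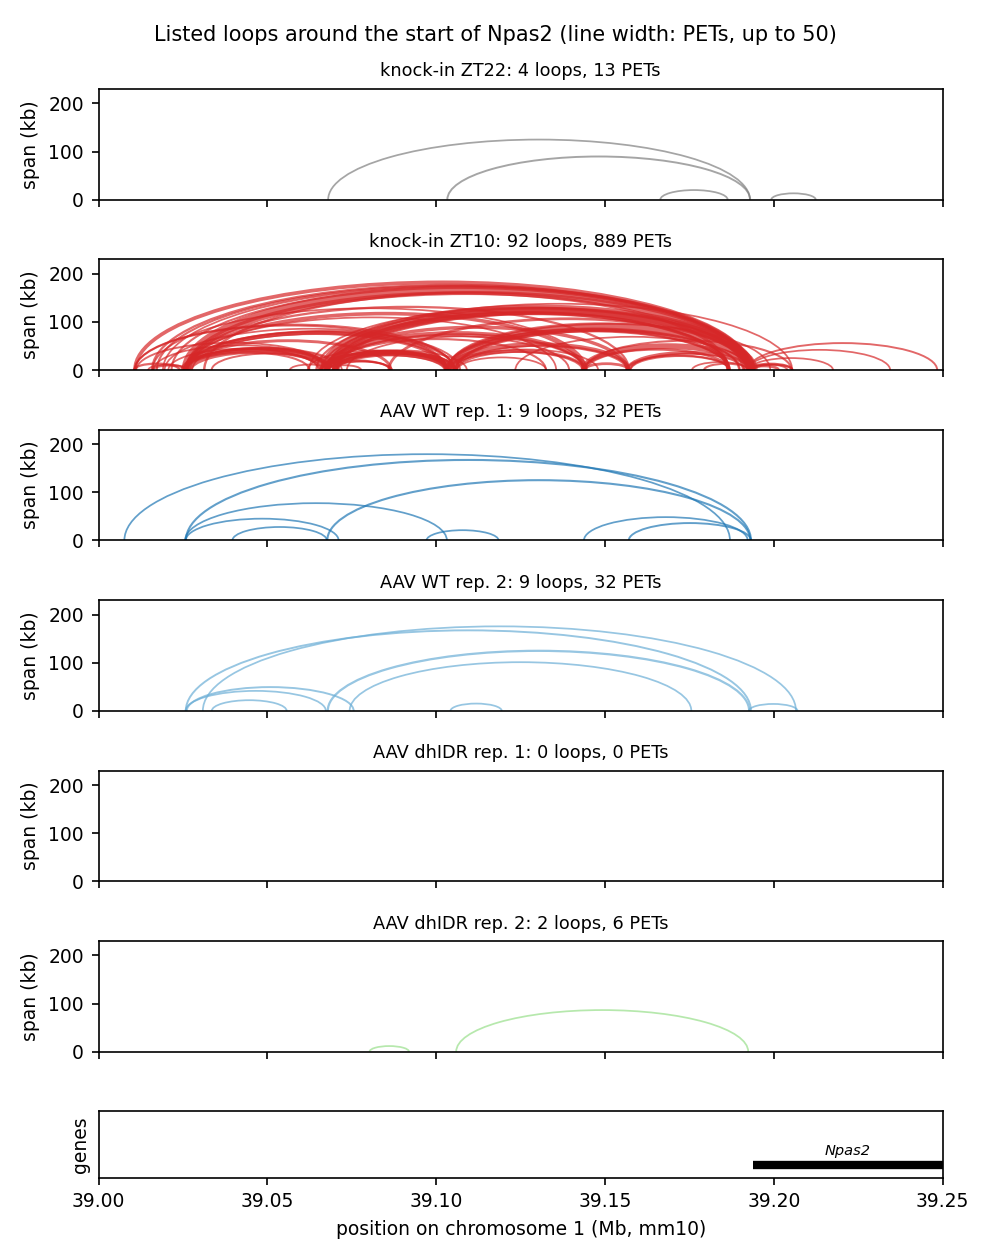
Arcs join the anchors of listed loops on chromosome 1 from 39 to 39.25 Mb in each of the 6 libraries (height: span in kb; line width: PETs, up to 50), over the part of Npas2 in that window. The ZT10 knock-in library lists 92 loops there, each WT replicate 9, and the dhIDR replicates 0 and 2.

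No gene list differed between WT and dhIDR by limma's camera, which called 0 of 14, with 1 at an unadjusted p under 0.05, and edgeR on list totals also called 0, with 1 under 0.05. By camera it was the endothelial list, lower in WT, with 18 and 40 PETs against 55 and 51 (adjusted p = 0.627 in limma's camera over 12 genes). Its unadjusted p was 0.172 with an estimated correlation, with which no list was called either. In edgeR totals it was the glucose list, with 39 and 82 PETs in WT and 48 and 28 in dhIDR (log2 0.81, SE 0.33, adjusted p = 0.357). Core clock genes had 44 and 75 against 73 and 74, lipogenesis 55 and 65 against 90 and 113, cholesterol and bile acid 48 and 75 against 73 and 35, fatty acid oxidation 34 and 42 against 49 and 58, and xenobiotic genes 25 and 32 against 53 and 33. Liver transcription factors had 44 and 89 PETs in WT against 85 and 39 in dhIDR, secreted proteins 46 and 47 against 75 and 49, acute-phase genes 28 and 54 against 43 and 33, Kupffer 22 and 59 against 46 and 29, stellate 16 and 82 against 76 and 20, cholangiocyte 12 and 36 against 6 and 34, and lymphocyte genes 10 and 42 against 37 and 35. Kupffer genes had a camera direction (lower in WT) opposite to that of their totals (log2 0.20). By fry's mixed p, which asks whether genes of a list change in either direction and does not compare them with other genes, the core clock had 0.00171 and acute-phase genes 0.00486. Endothelial genes had 0.0454 and glucose genes 0.0478. With the replicate number as a block these were 0.197, 0.0867, 0.186 and 0.355. By fry's directional p endothelial genes had 0.0301, and 0.227 with the block. None of these p-values is adjusted. Adjusted over the list alone, which for 1 gene is no adjustment, Npas2 was under 0.05 as the 1 core clock gene tested, and 0 of the other 3 list members tested (Dgat2, Acadm and Timd4) were. Over all genes tested, none was.

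Of the leading members of the lists, the 3 that were tested besides Npas2 (Dgat2, Acadm and Timd4) did not pass, and the rest are given as values. PETs in WT and dhIDR were 8 and 4 against 6 and 19 for Dgat2 (log2 -0.72, SE 1.06), 3 and 3 against 4 and 20 for Insig2, 12 and 12 against 10 and 5 for Abcb4, 11 and 10 against 3 and 6 for Slc27a5, 5 and 10 against 3 and 4 for Foxo1, and 3 and 12 against 0 and 6 for Ppargc1a. Acadm had 9 and 8 against 7 and 10 (log2 0.30, SE 1.01), Acadl 6 and 6 against 0 and 15, Ugt1a1 0 and 3 against 6 and 17, Abcc3 3 and 6 against 8 and 0, Nr5a2 0 and 28 against 10 and 0, Onecut2 12 and 7 against 4 and 6, Fga 3 and 0 against 7 and 13, and F2 4 and 3 against 12 and 3. Orm2 had 0 and 9 against 7 and 3, and Saa3 3 and 3 against 10 and 3. Among markers of other cells, Timd4 had 6 and 18 PETs in WT against 22 and 9 in dhIDR (log2 -0.12, SE 0.86), C1qb 5 and 0 against 3 and 14, Bmp2 0 and 22 against 4 and 9, Cdh5 6 and 9 against 14 and 0, Hand2 3 and 12 against 11 and 0, Lrat 3 and 9 against 0 and 13, Krt7 0 and 3 against 0 and 23, Cftr 3 and 9 against 3 and 5, Cd4 0 and 9 against 4 and 7, and Cd79a 4 and 3 against 6 and 5.

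Matched loops rarely recurred between the AAV libraries. Of 178786 matched loops, 178718 were listed in 1 library, 65 in 2, 1 in 3 and 2 in all 4. The last 2 lie in the chromosome 11 region and were the only loops that passed the count filter. One joined 3130287 to 3140250 with 3142196 to 3180659 (106 and 107 PETs in WT, 17 and 12 in dhIDR), and the other joined 3142196 to 3180659 with 3180837 to 3200608 (376 and 319 against 53 and 29). With TMM factors, which these 2 loops alone set, edgeR called 0, with 0 at an unadjusted p under 0.05 (adjusted p = 0.751), as did DESeq2. Scaled to total listed PETs, edgeR called both (log2 3.16, SE 0.59, and 3.43, SE 0.74, adjusted p = 0.00959), and without a count filter it called the second of them. Without dhIDR replicate 1 it called 4 other loops, on chromosomes 18, 1, 2 and 3, each listed in dhIDR replicate 2 alone with 15 or 16 PETs, a test in which the spread comes from the WT pair, at 0 for these loops, and the lone dhIDR library is taken to vary like it.

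Some whole-library measures overlapped between the constructs and others did not. Loops of at least 5 PETs numbered 2075 and 6801 in WT against 8488 and 8569 in dhIDR, and with each library thinned to the fewest listed PETs, loops numbered 31033 and 30711 against 28945 and 28234 (exact permutation p = 0.333 for both, n = 2 each). Mean PETs per loop were also lower in both WT than in both dhIDR libraries, as given above. Loops with both anchors at least 700 bp wide made up 5.89% and 3.49% of loops in WT and 1.61% and 0.669% in dhIDR. Most listed loops were thus narrower, and their PETs may be copies of single ligation products. These measures therefore do not separate the construct from library quality. As deposited, the median span was 893 ± 83.9 kb (SD, n = 2) in WT and 859 ± 300 kb in dhIDR (difference 34.4 kb, exact permutation p = 1), and the number of loops was 44568 ± 19141 against 44960 ± 4213 (exact permutation p = 1). Loops over 100 kb made up 73.0 ± 0.61% in WT and 74.5 ± 2.67% in dhIDR (n = 2 each, exact permutation p = 0.667), and loops per merged anchor were 1.05 ± 0.019 and 1.04 ± 0.0039 (exact permutation p = 1). Outside the chromosome 11 region, PETs with both anchors inside the anchors of ZT10 knock-in loops of at least 5 PETs made up 0.661% and 0.394% in WT, 1.01% and 0.565% in dhIDR, and 1.56% at ZT22 (exact permutation p = 0.667 between the constructs, n = 2 each). These shares were 6.96, 4.64, 11.8, 7.44 and 13.4 times those at shifted anchors. Among loops with both anchors at least 700 bp wide they were 4.41% and 3.44% in WT and 19.9% and 9.22% in dhIDR (exact permutation p = 0.333). With 2 against 2 libraries the smallest p is 0.333, so these tests can neither call a difference nor show that there is none. Without WT replicate 1 the difference in the number of loops, WT minus dhIDR, was 13142, without WT replicate 2 it was -13927, and it was positive also without dhIDR replicate 1.

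Differences by time of day and by construct showed little correlation across genes. Across 3062 genes with at least 10 PETs in each comparison, log2(ZT10/ZT22) and log2(WT/dhIDR) correlated at Spearman's rho -0.0546 and Pearson's r -0.0523. Genes are not independent replicates, and rho was -0.0152 without dhIDR replicate 1 and -0.0196 without WT replicate 2. With loops of at least 5 PETs rho was -0.107 and r -0.315 over 285 genes. PETs per gene correlated at a rho of only 0.141 between WT replicates and 0.148 between dhIDR replicates. A value near 0 therefore does not show that both changes are unrelated. Npas2 stood on the positive side of both.

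The knock-in and the AAV WT libraries, which both hold full-length tagged protein at ZT10, had few loops in common, and so had replicates of 1 construct. Of WT loops, 0.445 ± 0.113% (SD, n = 2) overlapped a ZT10 knock-in loop at both anchors, against 0.720% and 0.348% of dhIDR loops. Fewer still matched within a construct, 0.126% of WT replicate 1 loops in WT replicate 2 and 0.0271% of dhIDR replicate 1 loops in dhIDR replicate 2. PETs per gene in the ZT10 knock-in library correlated across 21887 genes, which are not independent replicates, at Spearman's rho 0.105 and 0.107 with WT, 0.177 and 0.120 with dhIDR, and 0.195 with ZT22. The WT replicates correlated with each other at 0.141 and the dhIDR replicates at 0.148. With only loops whose anchors were both at least 700 bp wide, 5.22% of WT loops overlapped a ZT10 loop, against 19.2% and 10.3% of dhIDR loops.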

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

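The tests of anchor width and of recurrence, and the loops with anchors at least 700 bp wide, were chosen only after the result was seen; both tests of the gene lists at ZT10 were written before theirs.

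Mitochondrial clusters, which the main comparisons left out, held 7300 PETs in the ZT22 and 49244 in the ZT10 knock-in library, 1207 and 1012 in the WT replicates, and 369 and 151 in the dhIDR replicates. They stand out because a chromatin-bound nuclear protein was pulled down, and no control library without antibody was used here to set a background. The lowest WT share of mitochondrial PETs was 2.39 times the highest dhIDR share, and the chromosome 11 region took 0.194% of PETs at ZT10 and 0.913% at ZT22; tests of that region against these values were run and left out of the weighing after their results were seen.

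In all libraries but the ZT10 knock-in one, the median anchor is about 600 bp wide at any number of PETs from 3 to 7, and in that library it is too among loops over 2 Mb (604 bp at 3 PETs and 597 bp at 6). PETs from independent ligations at a bound region would start at different cut sites and widen the anchors as they add up, as they did at ZT10, where the median at 7 PETs was 1.69 times that at 3 PETs in loops under 100 kb. In the other 5 libraries that ratio over all loops was at most 1.01, and mean PETs in loops over 2 Mb were at least 0.969 times those in loops under 20 kb. Copies of single ligation products counted as separate PETs would give both values. The width ratio restates the pattern itself, so it is no separate support for copies. Reads shared between near-identical places would list the same loops in several libraries, and 0.0380% of the matched AAV loops (68) were listed in more than 1, which argues against them; no biological explanation was tested.

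The 9 clock, metabolic and hepatocyte lists held more PETs at ZT10 than at ZT22. A larger library does not account for it, since with the ZT10 PETs thinned to the ZT22 total the lists still held 7342 against 574 PETs, a ratio of 12.8 (11.7 to 13.9). Dilution of the ZT22 library by narrow-anchor loops does not account for all of it, since among PETs of loops with wide anchors the lists took 5.39% at ZT10 and 0.654% at ZT22, a ratio of 8.24 (6.81 to 10.1). Both intervals take PETs as independent and may be too narrow. Binding of the protein near its peak at ZT10 remains open as a hypothesis, as does a difference in pulldown, sequencing depth or library quality, because each time has 1 library.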

How the results depend on the processing

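Alternatives chosen after seeing the data were the gene body, mitochondrial clusters kept, wide anchors (both at least 700 bp), list totals, removal of the chromosome 11 region, ZT10 thinned to ZT22, and PETs inside ZT10 anchors with its alternatives, as were the use of either gene end, the filter of the list tests and the tests named as such in the other parts. The other alternatives given here were fixed before the data were examined, and where a result moved the cause was not tested.

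For WT against dhIDR, genes called numbered 4 by DESeq2, 1 over gene bodies, and 0 to 3 with a replicate left out, which takes the lone library of a group to vary like the other pair. Loops called numbered 2 with total listed PETs, 1 without a filter and 0 to 4 with a replicate left out. No setting called a gene list. The replicate block called 0 genes, 0 loops and 0 lists and changed no call, though the smallest adjusted p over genes in edgeR went from 0.735 to 0.0705. Same-numbered libraries deviated together at a correlation of 0.0569. Replicates of a construct correlated at only 0.0719 (WT) and -0.165 (dhIDR), so this value cannot show whether the numbers mark a shared batch. The difference in median span (WT minus dhIDR) was 364 kb among spans over 20 kb, and -178 to 247 kb with a replicate left out. Left-out replicates moved the difference in loops from -13927 to 13142, in loops per anchor from -0.0112 to 0.0156, and in the percentage of PETs inside ZT10 anchors from -0.484 to -0.0378; with wide anchors the latter was -10.6.

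Genes higher at ZT10 numbered 2970 (25 kb), 536 (5 PETs per loop), 298 (median ratio), 1031 (at least 60 PETs), 669 (wide anchors) and 968 (thinned). Genes higher at ZT22 numbered 3 (2 kb), 491 (25 kb), 376 (median ratio), 3 (at least 60 PETs), 878 (gene body), 21 (wide anchors) and 4 (thinned). Shared ZT10 loops were 0.318% (5 PETs), 2.72% (10-kb bins), 0.721% (anchors overlapping by at least 50%) and 1.68% (thinned). Outlying lists numbered 2 with 2 kb and 2 with 25 kb. The correlation of both changes was -0.107 (5 PETs), -1 over the 6 genes with at least 50 PETs, and -0.0705 to -0.0152 with a replicate left out. WT loops in ZT10 made up 0.767% (5 PETs), 1.19% (10-kb bins) and 5.22% (wide anchors).

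Log2(ZT10/ZT22) reversed for Tdrd7 0.44, Utp14b 0.97, Acsl3 0.97 and Pecam1 -0.91 with 2 kb, and for Hlf -0.13, Nr1h4 -0.57, Saa3 -0.24 and Pecam1 -1.36 with the median ratio. In 9 further cases ZT22 was at 0 PETs, so the sign came from the pseudocount and scale and shows no reversal: Fhl3 0.23, Utp14b 0.59, Acsl3 0.59 and Sox9 -0.26 with 5 PETs, and Tdrd7 0.49 and Fhl3, Prg3, Utp14b and Acsl3 each 0.72 with wide anchors. Of the other values that answer no comparison by themselves, 767 were classed as unchanged, 72 moved, 50 were no longer called and 8 became called. The class of unchanged allows a change of sign, as for the difference in loops (-392.5 as deposited and 13142 without WT replicate 1). Few listed PETs per gene limited which genes the AAV comparison could test: filterByExpr left 333 of 21887 genes, and 2399 genes with at least 20 PETs or 18238 without a filter gave 0 calls too. The simulation changed depth and dispersion together, so it does not separate few PETs from spread between replicates.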

Other observations

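The test of Npas2 among wide-anchor PETs was chosen only after the result was seen, and that of the other hubs after Npas2 and 1 loop at another hub had been seen; the places named in the first paragraph were picked by rank from the ZT10 library.

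Outside the fibrinogen genes, the strongest loops of the ZT10 knock-in library included several within or beside single genes. A loop of 312 PETs joined 20930352 to 20946594 with 20954417 to 20971361 on chromosome 18 at Rnf125, a ubiquitin ligase gene. The next ones reached Slc34a2, a phosphate transporter gene (289 PETs), Prkce (251), the lysine catabolism gene Aass (233), the adrenergic receptor gene Adra1b (205), and Hopx (177). Nr1d1 itself, with its neighbour Thra, was joined to Msl1 by a loop of 184 PETs between 98771559 to 98778389 and 98781899 to 98791474 on chromosome 11. The anchor with the most loops was that of Npas2, at 39188588 to 39196072 on chromosome 1, with 37 loops and 509 PETs. Next came an anchor with no protein-coding gene within 5 kb at 24220701 to 24229918 on chromosome 16 (33 loops), and those at Dusp6 (28 loops) and Bcl6 (27 loops) were also among the first 10.

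Some loops that recurred among the AAV libraries were also loops of the knock-in. Outside the chromosome 11 region, 64 matched loops were listed in more than 1 AAV library, and 15 of them (23.4%) overlapped a ZT10 knock-in loop at both anchors, against 0.348% to 0.720% of all loops of an AAV library. Anchors of recurrent loops are merged over libraries and so are wider, and among loops with both anchors at least 700 bp wide 5.30% and 5.13% of WT and 19.2% and 10.3% of dhIDR loops did so. Of the 64, 12 were shared by the WT pair (3 of them in ZT10), 9 by the dhIDR pair (3 in ZT10) and 43 by a WT and a dhIDR library (9 in ZT10).

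Npas2 had more PETs in both WT than in both dhIDR libraries, and one hypothesis was that hubs of the ZT10 network in general need the full-length protein. At the other 9 of the 10 anchors with most ZT10 loops, WT libraries had 28 and 22 PETs and dhIDR libraries 36 and 32, a ratio per listed PET of 0.809 (counting interval 0.550 to 1.18). That interval met the bound written for excluding such a need, but a condition on single libraries, added after the result was known, left it open: PETs that may be copies make the interval too narrow, and per 10,000 listed PETs one WT library (2.69) lay above both dhIDR libraries (2.02 and 1.99) and the other (1.08) under them. Fewer wide-anchor PETs in the dhIDR libraries may account for the difference at Npas2. Wide-anchor loops there held 27 PETs in WT and 3 in dhIDR, and as a share of all wide-anchor PETs the ratio was 2.40 (0.737 to 12.3). Npas2 also did not pass the gene test (adjusted p = 0.735 in edgeR), and its loops were looked at after its counts were seen. With 3 PETs, fewer wide-anchor PETs, a need for the hIDR at Npas2 and chance cannot be told apart.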
